A study of Mus musculus with 20 samples.

How the data were processed

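Total RNA of 20 mouse samples was hybridised to Affymetrix Mouse 430 2.0 arrays, 2 per group. Per the labels, RNA of MPP, CDP, cDC and pDC (1 µg each) was labelled with a one-cycle kit. RNA of the TGF-β1 series (250 ng) and of in vivo CDP (50 ng) was labelled with a 3′ IVT kit, and the in vivo RNA was extracted with another kit. The dose of TGF-β1 and the numbers of mice and cultures are not given in the sources used here.

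The deposited values are log2 probe set intensities, background-adjusted and normalized by the authors, with GCRMA named in the submitters' processing notes; its version is not given in the sources used here. Of the 20 arrays, 10 shared one floor value and the 10 TGF-β1 arrays did not. The values of the latter may have been made in another run or by another method, which is not given in the sources used here. The table held 45101 probe sets, 64 of them array controls. A platform annotation of 2016 gave 34958 probe sets 1 gene symbol and 932 several, and 9211 were not named. Each of 18194 genes was represented by its probe set with the highest mean over the 20 arrays, which was a choice for 9012 genes with more than 1. The deposited values were used without further scaling.

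Differences were computed with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off), with separate fits for the 8 one-cycle arrays, the 10 TGF-β1 arrays, and the 10 arrays that share the floor. The planned comparison of in vivo CDP with 0 h used a fit of 12 arrays, and that between kits a fit of all 20. Genes were tested if their value was above 5 on at least 2 arrays of the fit. Adjusted p is Benjamini-Hochberg over the genes tested, two-sided, with a threshold of 0.05, and a moderated F-test covered all TGF-β1 times. Levels are mean ± SD with n = 2 arrays per group, differences are in log2 units with limma's SE, and folds are unlogged differences. Where both arrays of the lower group were under 5, the fold was computed against 5 and is given as "at least". The p-value beside such a fold tests the full difference in deposited values, not the bound. Arrays that share the floor value add no spread, which can lower it. On the TGF-β1 arrays 54.4% to 56.0% of probe sets lay above 5, against 34.0% to 35.2% on the other arrays. The same level of 5 thus screens out less there, and folds from levels just above it are uncertain.

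Gene lists were fixed along with the comparisons, tests and named genes before the data were examined. They were TGF-β SMAD response, cDC markers, pDC markers, MHC class II presentation, maturation and costimulation, stem and progenitor, cytokine receptors, cell cycle, MYC and ribosome biogenesis, interferon response, immediate early and stress, sterol synthesis, and markers of granulocytes, mast cells and basophils, monocytes and macrophages, erythroid cells, megakaryocytes, B cells, T and NK cells, and eosinophils. Of 381 list genes 351 had a measured value. Lists with at least 5 tested members were compared with all other genes by camera (inter-gene correlation 0.01) and, beside it, with an estimated correlation, each adjusted over the lists of a comparison. This left 15 lists for the one-cycle fits, without erythroid, megakaryocyte, B cell, T and NK cell and eosinophil markers, and 19 for the TGF-β1 fit. The sets higher in cDC or pDC, and in cDC or CDP, held genes called on the one-cycle arrays with a log2 difference of at least 2, and were tested on the TGF-β1 arrays with the same tests, adjusted over these 4 sets.

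The genes named are the 8 with the largest increase and the 8 with the largest decrease among called genes whose arrays did not overlap, up to 2 called members per list and direction, and a fixed set of regulators (Id2, Irf4, Irf8, Batf3, Relb, Spib, Tcf4, Flt3, Csf1r, Kit and Gfi1, with Smad7, Skil, Tgfbr1 and Tgfbr2 for TGF-β1). For the earlier times they are the 4 with the smallest p in each direction and those named for 24 h. The comparison of in vivo CDP with one-cycle CDP, and the removal of 3 arrays with low 5′ signal or a Gapdh covariate, were chosen after the data were seen.

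Whether replicate numbers pair arrays was checked by correlating deviations from the group means between groups. Correlations were 0.27 to 0.85 in the TGF-β1 arrays and -0.06 to 0.58 in the one-cycle arrays. The highest TGF-β1 values, 0.67 to 0.85, were those among 4, 12 and 24 h, against 0.27 to 0.54 for the other pairs. Replicate 1 of these times had low 5′ signal, so a block may take up that difference as well as any pairing. The value for 0 h with 8 h, where no array had low 5′ signal, was 0.54, against 0.27 to 0.32 for 0 h with 4, 12 and 24 h. Low 5′ signal does not account for that value, so the fits without a block may leave out a shared replicate effect. Values with the number as a block are given for the TGF-β1 series. The highest one-cycle values were 0.58 for MPP with CDP and 0.44 for cDC with pDC, and for these arrays blocked values are given where a list or named gene changed its call. The other one-cycle values were -0.06 to 0.11. The block was a single term common to all 8 arrays, so it may not take up separate pairings of MPP with CDP and of cDC with pDC. The fits were tested on simulated data with 100 changed genes of each size. Of genes changed by 1 log2 unit, 33% were recovered for CDP versus MPP, 30% for cDC versus CDP, 34% for pDC versus CDP, 29% for cDC versus pDC, 45% at 4 h, 38% at 24 h, 31% for 24 h versus 4 h and 37% in vivo. Of genes changed by 2 units, 78% to 84% were recovered, with 3 to 9 false calls. The simulated noise was normal and independent between arrays, and a gene had the same SD in all groups. It held no floor, low 5′ signal or shared replicate effect, so recovery and false calls on the real arrays may differ. The alternatives tried were other filters, quantile normalization, median centring, another variance model, other probe set choices, all arrays in 1 fit, a replicate block, other list sizes and set tests, and leaving out each array in turn. Where leaving out arrays left 1 in a group, that array was assumed to vary like the groups that kept both.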

Results

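RNA from 20 samples of mouse dendritic cell lineages was measured on Affymetrix Mouse 430 2.0 arrays, with 10 groups of 2 arrays each. Progenitors amplified in culture from C57BL/6 bone marrow gave 2 groups, the multipotent progenitor (MPP) and the common dendritic cell progenitor (CDP). Conventional dendritic cells (cDC), which present antigen to T cells, and plasmacytoid dendritic cells (pDC), which make type I interferon, were grown from such progenitors. A separate series of cultured CDP was left untreated (0 h) or given the cytokine TGF-β1 for 4, 8, 12 or 24 h. No untreated culture of 4 to 24 h was among the samples, so hours in culture and TGF-β1 cannot be told apart in this series. The last group was CDP taken directly from bone marrow (in vivo CDP). The series title names the purpose: whether TGF-β1 speeds differentiation of CDP and favours cDC over pDC. The number of arrays limits the precision of every value, and nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these arrays.

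The deposited table had 2 parts. The 8 arrays of MPP, CDP, cDC and pDC and the 2 in vivo arrays shared a lowest log2 value of 2.25, held by 33.8% to 35.6% of probe sets. The 10 TGF-β1 arrays had no such floor, and their medians lay between 5.29 and 5.36 against 2.46 to 2.52 in the other part. Cultured untreated CDP of both parts differed at 9373 of 12825 genes, 8359 of them higher at 0 h, with a median difference of 1.31. Centring each array on its median left 65.6% of the changed genes higher in place of 89.2%, and quantile normalization left 49.3%. The planned comparison of in vivo CDP with CDP at 0 h crosses the same border and gave 8596 of 12696 genes, 10.9% of them higher in vivo, or 30.0% after centring and 46.3% after quantile normalization. Beyond these counts, levels are therefore given within a part, and in vivo CDP is set against the cultured CDP of its own part and, only after quantile normalization, against CDP at 0 h.

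Within the TGF-β1 series, replicate 1 at 4, 12 and 24 h had low signal at the 5′ end of control transcripts. The difference between the 3′ and 5′ Gapdh probe sets was 2.09, 2.61 and 2.78 on the log2 scale on these arrays and between 0.01 and 0.10 on the other 7. Beta-actin differed by 1.89 to 2.11 against 0.19 to 0.35. A replicate SD was computed over genes from the difference between both arrays of a group and scaled to 1 array. It was 0.15 at 0 h, 0.51 at 4 h, 0.20 at 8 h, 0.31 at 12 h and 0.37 at 24 h. The same beta-actin difference was 1.91 and 2.04 in MPP, 1.23 and 2.11 in CDP, 0.69 and 0.84 in cDC, 0.84 and 0.94 in pDC, and 1.39 and 1.09 in in vivo CDP. For Gapdh it was 0.98 and 0.47 in in vivo CDP against -0.15 and 0.19 in CDP, and for the transferrin receptor 3.82 and 3.71 against 1.94 and 2.49.

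**Figure D1:**
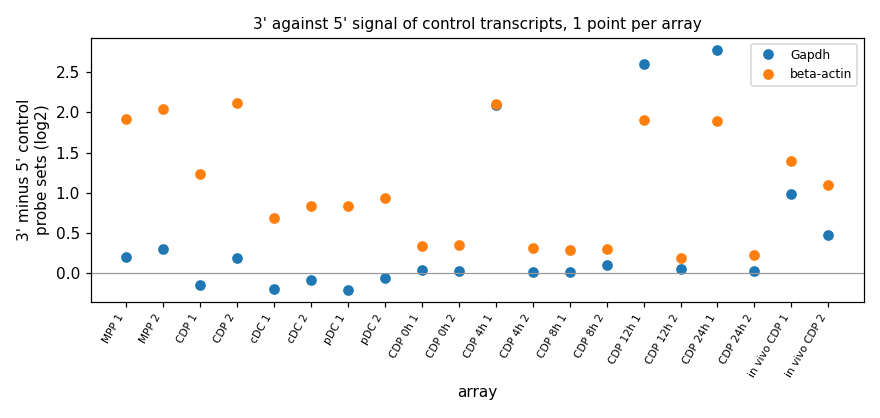
Difference between the 3′ and 5′ probe sets of Gapdh and beta-actin on each array, in log2 units. Replicate 1 at 4, 12 and 24 h stands above the other TGF-β1 arrays, with Gapdh differences of 2.09, 2.61 and 2.78.

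The step from MPP to CDP was marked by loss of granulocyte and mast cell genes. Myeloperoxidase (Mpo), an enzyme of neutrophil granules, fell from 14.68 ± 0.02 in MPP to 8.60 ± 0.00 in CDP (67.3-fold lower, SE 0.16 on the log2 scale, adjusted p = 1.42e-05). Neutrophil elastase (Elane) was at least 75.9-fold lower, and the mast cell protease Cpa3 at least 29.1-fold lower. The receptor for stem cell factor, Kit, fell by 4.67 (SE 0.27, adjusted p = 1.57e-04), and the transcriptional repressor Gfi1 fell by 4.26 (SE 0.23, adjusted p = 1.39e-04). The LIF receptor gene Lifr rose from 2.38 ± 0.12 to 8.80 ± 0.16, at least 14.0-fold. Ly86, a partner of a Toll-like receptor homologue, was 49.5-fold higher, and the lysosomal protease Lgmn was at least 22.8-fold higher. Flt3, the receptor for the main growth factor of dendritic cells, was higher by 2.90 (SE 0.26, adjusted p = 0.00104).

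Of 14 measured granulocyte markers, 13 were lower in CDP and 1, Mmp8, was higher by 3.30, with the same counts adjusted over the list alone. Their median difference was -4.62, or -3.17 with values under 5 raised to 5 (adjusted p = 4.88e-14; adjusted p = 0.113 with an estimated correlation). Among 7 mast cell and basophil markers, 5 were lower (7 adjusted over the list alone), with Hdc at least 21.8-fold and Ms4a2 at least 5.52-fold lower (adjusted p = 1.17e-08; adjusted p = 0.113 with an estimated correlation). Of 18 stem and progenitor genes, 9 were lower and 1, Egfl7, was higher by 1.66 (11 and 1 adjusted over the list alone; median -1.01, adjusted p = 3.94e-08; adjusted p = 0.113 with an estimated correlation). In the other direction, 5 of 17 pDC markers were higher (6 adjusted over the list alone), among them Tcf4, a factor needed for pDC, by 1.39, and Bcl11a by 1.66 (adjusted p = 1.23e-04; adjusted p = 0.219 with an estimated correlation). Their median of 0.96 became 0.00 with values under 5 raised to 5. Of 19 cDC markers, 4 were higher (4 adjusted over the list alone), including Id2 by 2.73 and Dpp4 by 3.17 (median 0.80, or 0.17 with low values raised; adjusted p = 1.98e-04; adjusted p = 0.261 with an estimated correlation).

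Of 16 immediate early and stress genes, 3 were higher in CDP (6 adjusted over the list alone), with Socs3 higher by 1.71 (median 1.09, adjusted p = 2.95e-04; adjusted p = 0.357 with an estimated correlation). Receptors for haematopoietic cytokines split, with 5 of 16 higher and 3 lower (7 and 3 adjusted over the list alone), and Il7r at least 1.11-fold higher (adjusted p = 0.0172; adjusted p = 0.219 with an estimated correlation). The TGF-β SMAD list had 4 of 21 higher and 1 lower (5 and 1 adjusted over the list alone), with Id3, an inhibitor of E proteins, at least 26.7-fold higher (adjusted p = 0.0120; adjusted p = 0.565 with an estimated correlation). Of 14 MHC class II genes 3 were higher (4 adjusted over the list alone), including Ctss by 2.33 (adjusted p = 0.00957; adjusted p = 0.577 with an estimated correlation). Of 11 monocyte and macrophage markers 2 were higher (3 adjusted over the list alone), Cx3cr1 by 2.96 and Cd68 by 1.74 (adjusted p = 0.0161; adjusted p = 0.565 with an estimated correlation). The 29 cell cycle genes had a median of 0.30 with 0 members past limma's adjusted threshold and 2 past an unadjusted one (adjusted p = 0.00957; adjusted p = 0.577 with an estimated correlation). No call was made for the interferon (adjusted p = 0.963, median -0.12 with the test pointing up), sterol (adjusted p = 0.0863) or MYC (adjusted p = 0.172) lists, with the block of replicate numbers or without it, although Myc itself fell by 2.62. The maturation list (median 0.37, adjusted p = 0.0818) passed with the replicate number as a block (adjusted p = 0.0219; adjusted p = 0.552 with an estimated correlation), with 3 of 14 genes higher in that fit. Its member Cd86 (2.58, adjusted p = 0.104) passed at 0.00777 when blocked, and Relb, which stood at 3.12 in MPP and 4.59 in CDP (adjusted p = 0.289), at 0.0429.

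In all, limma called 668 of 8901 genes between CDP and MPP, 355 higher and 313 lower in CDP, of which 319 and 271 differed at least 2-fold, or 746 with the replicate number as a block. The count was 208 without MPP replicate 1, 222 without MPP replicate 2 and 435 without CDP replicate 1.

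Differentiation from CDP to cDC raised antigen presentation genes and lowered granulocyte and proliferation genes. The MHC class II chain H2-Eb1 reached 14.42 ± 0.09 in cDC against 5.65 ± 1.65 in CDP, 436-fold higher (SE 0.66 on the log2 scale, adjusted p = 1.66e-04), and H2-Ab1 was 381-fold higher. Fascin (Fscn1), an actin-bundling protein of mature dendritic cells, was at least 229-fold higher, the maturation marker Cd83 at least 135-fold and the chemokine Ccl5 at least 95.8-fold. Cathepsin G (Ctsg), a granulocyte protease, stood at 13.28 ± 0.50 in CDP and was at least 311-fold lower in cDC (adjusted p = 7.28e-06). Of the transcription factors, Irf4 was at least 11.9-fold, Spib at least 30.4-fold and Batf3 at least 2.80-fold higher. Id2 rose by 1.97 (SE 0.39), Irf8 by 2.06 (SE 0.27) and Relb by 3.38 (SE 0.67), while Tcf4 differed by 0.03 (adjusted p = 0.906). Kit was 66.9-fold higher in cDC, at 11.10 ± 0.30 against 5.03 ± 0.40 (adjusted p = 2.59e-05), and Gfi1 was at least 2.23-fold lower.

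Of 19 cDC markers, 18 were higher in cDC and 1, Nfil3, was at least 4.32-fold lower, with the same counts adjusted over the list alone. Itgae (CD103) was at least 26.4-fold and the chemokine receptor Xcr1 at least 4.26-fold higher (median 4.83, or 3.23 with values under 5 raised to 5; adjusted p = 2.64e-10; adjusted p = 0.225 with an estimated correlation). Of 14 MHC class II genes 13 were higher, in the list alone too, among them the class II transactivator Ciita by at least 20.3-fold (median 5.28, adjusted p = 1.05e-09; adjusted p = 0.266 with an estimated correlation). Maturation and costimulation genes were higher for 13 of 14 (14 adjusted over the list alone; median 3.88, or 2.49 with low values raised; adjusted p = 2.05e-08; adjusted p = 0.225 with an estimated correlation). Of 17 pDC markers, 13 were higher in cDC than in CDP and 2 lower, with the same counts adjusted over the list alone; Upb1 was at least 3.01-fold higher and Cox6a2 107-fold lower (adjusted p = 2.17e-05; adjusted p = 0.225 with an estimated correlation). Klk1, also on this list, was lower in cDC by the probe set used but not by another. Interferon response genes were higher for 9 of 18 (10 adjusted over the list alone), with Mx1 at least 50.2-fold higher and Irf9 higher by 3.17 (adjusted p = 2.26e-05; adjusted p = 0.409 with an estimated correlation).

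The cell cycle list fell in 27 of 29 members, with the same count adjusted over the list alone, including the replication gene Cdc45 by -1.93 (median -1.50, adjusted p = 2.60e-07; adjusted p = 0.310 with an estimated correlation). MYC and ribosome biogenesis genes were lower for 16 of 20 and higher for 1 (17 and 1 adjusted over the list alone). Srm, an enzyme of polyamine synthesis, fell by 2.63 while Myc rose by 1.22 (median -1.39, adjusted p = 6.83e-05; adjusted p = 0.266 with an estimated correlation). Of 14 granulocyte markers 9 were lower, in the list alone too, and of 18 stem and progenitor genes 10 were lower and 1 higher, with Myb lower by -3.75. Their tests gave adjusted p = 4.85e-05 and adjusted p = 0.00415 (both adjusted p = 0.266 with an estimated correlation). Of 16 immediate early genes 10 were higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 0.00101; adjusted p = 0.311 with an estimated correlation). Cytokine receptors were higher for 7 of 16 and lower for 3 (8 and 3 adjusted over the list alone), with Il7r 20.1-fold higher (adjusted p = 0.00581; adjusted p = 0.225 with an estimated correlation). The SMAD list split into 5 higher and 7 lower of 21 (adjusted p = 0.951). No list call was made for monocyte (3 higher, 1 lower of 11), sterol (1 lower of 17) or mast cell markers (median 0.31 and mean -0.04), of which 1 of 7 was higher, Hdc (adjusted p = 0.0497, or 0.0596 with the replicate number as a block).

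Limma called 4269 of 8901 genes between cDC and CDP, 1661 higher and 2608 lower, of which 1162 and 1690 differed at least 2-fold. The all-gene median difference of -0.16 became -0.03 when arrays were centred on their medians, and the beta-actin 3′ to 5′ difference was smaller in cDC than in CDP.

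In pDC, the largest increases over CDP included known pDC genes. The gut-homing receptor Ccr9 stood at 13.58 ± 0.53 against 2.25 ± 0.00, at least 384-fold higher (adjusted p = 1.52e-05). Ly6d was at least 435-fold, the lectin Siglech at least 289-fold and the transcription factor Spib at least 259-fold higher. Irf8 was 12.7-fold higher (SE 0.27 on the log2 scale, adjusted p = 9.65e-05), and Tcf4 was 5.14-fold higher (SE 0.18, adjusted p = 1.17e-04). The IL-7 receptor Il7r was 243-fold higher and Dntt, the enzyme that adds bases at V(D)J junctions, at least 42.3-fold. Ctsg was at least 311-fold lower, asparagine synthetase (Asns) at least 269-fold and Tgfbi 264-fold lower. Id2 fell by 1.62 (SE 0.39, adjusted p = 0.0114), while another probe set of the gene was higher in pDC by 1.20. Csf1r fell by 3.51, Flt3 was higher by 0.79 and Kit by 0.92, while Batf3 (adjusted p = 0.116) and Relb (adjusted p = 0.370) did not pass.

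Of 17 pDC markers, 15 were higher and 1 lower, with the same counts adjusted over the list alone (median 5.91, or 5.12 with values under 5 raised to 5; adjusted p = 2.62e-09; adjusted p = 0.290 with an estimated correlation). Klk1, a member of this list, was lower in pDC by the probe set used and higher by another. MHC class II genes were higher for 11 of 14 and lower for 1, the protease Lgmn (12 and 1 adjusted over the list alone). H2-Ab1 was 39.6-fold higher (median 2.89, adjusted p = 1.35e-04; adjusted p = 0.515 with an estimated correlation). Interferon response genes were higher for 7 of 18 (6 adjusted over the list alone), with Bst2 higher by 5.12 (adjusted p = 0.00141; adjusted p = 0.670 with an estimated correlation). Sterol synthesis genes were higher for 9 of 17 and lower for 1, with the same counts adjusted over the list alone, including Hmgcs1 by 2.15 and Sc5d by 2.28 (median 1.46, adjusted p = 0.00520; adjusted p = 0.670 with an estimated correlation).

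Cell cycle genes were lower for 27 of 29 (28 adjusted over the list alone), with Cdc6 lower by -3.27 (median -2.29, adjusted p = 2.62e-09; adjusted p = 0.343 with an estimated correlation). Of 20 MYC and ribosome biogenesis genes 17 were lower (18 adjusted over the list alone), Myc itself by at least 8.62-fold (adjusted p = 5.30e-06; adjusted p = 0.343 with an estimated correlation). Granulocyte markers were lower for 9 of 14 and stem and progenitor genes for 11 of 18, with 1 of the latter higher; Cd34 was at least 17.9-fold lower. These tests gave adjusted p = 1.35e-04 and adjusted p = 0.00520 (both adjusted p = 0.343 with an estimated correlation). No call was made for cDC markers (8 higher, 2 lower of 19; adjusted p = 0.0561), cytokine receptors (8 higher, 4 lower of 16; adjusted p = 0.0537), the SMAD list (4 higher, 9 lower of 21; adjusted p = 0.473) or immediate early genes (3 higher, 5 lower of 16). Maturation genes (2 higher, 1 lower of 14) and monocyte markers (4 higher, 3 lower of 11) also stayed without a call, as did mast cell markers (1 lower of 7).

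Limma called 4739 of 8901 genes between pDC and CDP, 1930 higher and 2809 lower, of which 1362 and 2000 differed at least 2-fold. The all-gene median of -0.14 became -0.01 with median centring, and the beta-actin 3′ to 5′ difference was smaller in pDC than in CDP.

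**Figure D2:**
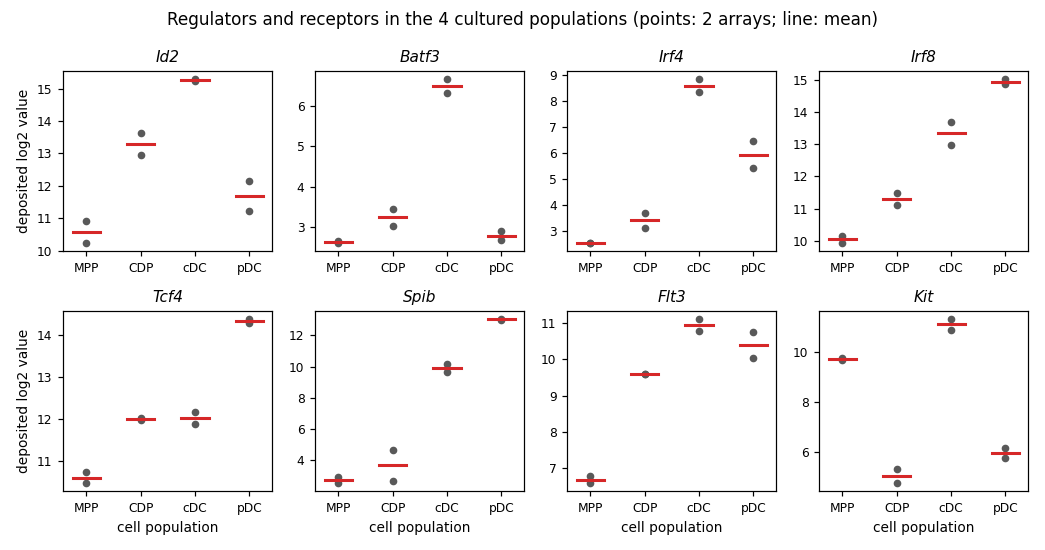
Log2 expression of 8 genes in MPP, CDP, cDC and pDC, with points for the 2 arrays and a line at their mean. Kit is highest in MPP and cDC, Tcf4 and Irf8 are highest in pDC, and Id2 and Batf3 are highest in cDC.

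The direct comparison of both dendritic cell types separated them by their known markers. Cd83 was at least 135-fold, the double-stranded RNA receptor Tlr3 at least 41.9-fold and the cytokine Il1b at least 42.0-fold higher in cDC. Plbd1 was 204-fold and Ifitm6 158-fold higher in cDC (adjusted p = 0.00291 and adjusted p = 1.32e-04). In pDC, Ccr9 was higher by 7.25 log2 units, which reads as -7.25 for cDC minus pDC (SE 0.50, adjusted p = 1.24e-04), and Ly6d by 101-fold. Id2 was 12.0-fold higher in cDC (SE 0.39 on the log2 scale, adjusted p = 8.12e-04), Irf4 higher by 2.65 (SE 0.38) and Relb at least 7.85-fold higher. Irf8 differed by -1.61 (SE 0.27), Spib by -3.09 (SE 0.57) and Tcf4 by -2.33 (SE 0.18), all lower in cDC. Kit was 35.3-fold higher in cDC, whereas Flt3 differed by 0.54 (adjusted p = 0.188) and Csf1r by 2.06 (adjusted p = 0.123).

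Of 19 cDC markers 16 were higher in cDC, and of 17 pDC markers 15 were lower, with the same counts adjusted over each list alone. The medians were 3.59 and -3.09 (adjusted p = 5.40e-09 and adjusted p = 2.62e-09; both adjusted p = 0.247 with an estimated correlation). Maturation genes were higher in cDC for 13 of 14 (14 adjusted over the list alone; median 4.29, or 3.19 with values under 5 raised to 5; adjusted p = 2.82e-09; adjusted p = 0.252 with an estimated correlation). MHC class II genes were higher for 8 of 14 (12 adjusted over the list alone), with Ciita at least 20.3-fold (adjusted p = 1.46e-06; adjusted p = 0.487 with an estimated correlation). Cell cycle genes were higher in cDC for 12 of 29 (17 adjusted over the list alone), with Mcm4 higher by 1.48 and Cdc6 by 1.28 (median 0.77, adjusted p = 1.67e-06; adjusted p = 0.533 with an estimated correlation). Immediate early genes were higher for 10 of 16 (12 adjusted over the list alone), among them Junb by 3.09 and Nr4a1 by 2.83 (adjusted p = 1.29e-05; adjusted p = 0.436 with an estimated correlation). Sterol synthesis genes were lower in cDC for 8 of 17 (11 adjusted over the list alone), with Hmgcs1 at -1.46 (median -1.55, adjusted p = 4.22e-04; adjusted p = 0.739 with an estimated correlation). No call was made for the SMAD list (adjusted p = 0.287), in which Tgfbr1 was lower by -2.96, nor for stem, receptor, MYC, interferon or monocyte genes. Granulocyte and mast cell markers had 1 higher member each, of 14 and 7.

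Limma called 2273 of 8901 genes between cDC and pDC, 1142 higher in cDC and 1131 higher in pDC, of which 868 and 789 differed at least 2-fold. The count was 1262 without pDC replicate 1, 1343 without cDC replicate 1 and 1474 without cDC replicate 2.

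After 24 h of TGF-β1, E-cadherin (Cdh1) rose from 5.72 ± 0.47 to 12.32 ± 0.15, 97.3-fold (SE 0.36 on the log2 scale, adjusted p = 5.50e-05). Itgae, whose product binds E-cadherin, rose from 5.20 ± 0.17 to 11.38 ± 0.32, 72.6-fold (SE 0.51, adjusted p = 2.57e-04). Both 0 h levels lay near the medians of these arrays (5.29 to 5.36), where signal may be background, so the folds are uncertain. The tight junction gene Cldn1 rose at least 15.6-fold, Gna14 at least 45.1-fold, and Pmepa1, a SMAD target that dampens the pathway, at least 54.0-fold. Ctsg fell by 4.38 (SE 0.29, adjusted p = 9.90e-05), haptoglobin (Hp) by 4.64 (SE 0.48, adjusted p = 6.87e-04), and lysozyme (Lyz2) by 3.32. The TGF-β receptors rose, Tgfbr1 7.61-fold and Tgfbr2 by 2.52 (SE 0.26), and so did the feedback regulators Skil by 2.58 (SE 0.26) and Smad7 by 2.16 (SE 0.48).

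Among the transcription factors of dendritic cells, Irf4 rose 6.58-fold (SE 0.26 on the log2 scale, adjusted p = 4.44e-04). Id2 rose by 1.60 (SE 0.43, adjusted p = 0.0344), Batf3 by 1.65 (SE 0.41, adjusted p = 0.0277) and Relb by 1.24 (SE 0.27, adjusted p = 0.0148). Irf8 (0.27, adjusted p = 0.601), Spib (0.08, adjusted p = 0.857) and Tcf4 (-0.20, adjusted p = 0.663), all higher in pDC than in cDC, did not pass. On the one-cycle arrays Irf8 and Spib were also higher in cDC than in CDP, so they do not mark pDC alone. Of the growth factor receptors, Flt3 rose by 1.06 (SE 0.15, adjusted p = 0.00288), Csf1r by 0.91 and Kit by 1.59 (SE 0.31, adjusted p = 0.00920), and Gfi1 fell by 1.11.

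At 24 h, 11 of 14 MHC class II genes rose (11 adjusted over the list alone), including H2-Ab1 by 2.75 (SE 0.29) and Ciita by 1.86 (SE 0.17), with a median of 1.86 (adjusted p = 1.71e-06; adjusted p = 0.0667 with an estimated correlation). Of 19 cDC markers 10 rose and 1, Nfil3, fell (11 and 1 adjusted over the list alone; median 0.88, adjusted p = 0.00117; adjusted p = 0.0667 with an estimated correlation). Of 18 pDC markers 5 rose (5 adjusted over the list alone), including Smim5 by 2.69 and Pacsin1 by 1.70 (median 0.11, adjusted p = 0.141). Maturation genes rose for 8 of 14 (9 up and 1 down adjusted over the list alone), with Cd40 up by 2.34 (adjusted p = 6.86e-04; adjusted p = 0.154 with an estimated correlation). The SMAD list had 11 of 23 up and 4 down (11 and 5 adjusted over the list alone), with Bhlhe40 up 8.49-fold and Id1 and Smad3 down by -3.79 and -1.88 (adjusted p = 0.00818; adjusted p = 0.0734 with an estimated correlation). Cytokine receptors rose for 7 of 19 and fell for 1, Csf3r (7 and 1 adjusted over the list alone; adjusted p = 0.0203; adjusted p = 0.107 with an estimated correlation). Sterol synthesis genes rose for 5 of 17 (6 adjusted over the list alone), with Hmgcs1 up by 0.77 (adjusted p = 0.00221; adjusted p = 0.204 with an estimated correlation).

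Genes of ribosome production fell, with 15 of 20 MYC and ribosome biogenesis genes lower at 24 h (18 adjusted over the list alone). The nucleolar genes Nolc1 and Nop58 fell by 2.73 and 2.15 (list median -1.81, adjusted p = 2.21e-12; adjusted p = 0.0667 with an estimated correlation). Cell cycle genes fell for 6 of 29 (6 adjusted over the list alone), with Cdc6 at -1.35 (median -0.58, adjusted p = 2.18e-04; adjusted p = 0.0667 with an estimated correlation). Of 15 granulocyte markers 3 fell (4 adjusted over the list alone), among them Ctsg and Ms4a3, the latter at -1.78 (adjusted p = 0.00289; adjusted p = 0.0667 with an estimated correlation). Stem and progenitor genes fell for 6 of 19 and rose for 2 (7 and 2 adjusted over the list alone), with Egfl7 at -2.31, Cdk6 at -1.56 and Gata2 at 1.36 (adjusted p = 0.0178; adjusted p = 0.0878 with an estimated correlation). Immediate early genes fell for 5 of 16 (6 adjusted over the list alone), with Hspa1b at -1.98 (adjusted p = 0.0102; adjusted p = 0.0797 with an estimated correlation), and monocyte and macrophage markers for 2 of 11, Lyz2 and Fcgr1 (5 adjusted over the list alone; adjusted p = 0.0297; adjusted p = 0.302 with an estimated correlation).

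Marker lists of other blood cells made no call at 24 h. Of 20 interferon response genes 3 rose and 1 fell (adjusted p = 0.242). Erythroid markers had 2 up, including Car2 by 2.24, and 1 down of 7 (adjusted p = 0.428). Megakaryocyte markers had 1 up of 10, Vwf by at least 6.66-fold (median -0.01, mean 0.34, test pointing up, adjusted p = 0.428). B cell markers had 2 up and 1 down of 8 (adjusted p = 0.470), and T and NK cell markers 2 up of 9, including Cd5 by 2.11 (adjusted p = 0.428). The 5 mast cell and basophil markers had a median of -0.03 (adjusted p = 0.678). Fewer than 5 eosinophil markers were measured, so the list was not tested; Siglecf rose 13.7-fold (SE 0.47 on the log2 scale, adjusted p = 0.00146).

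Limma called 2436 of 12656 genes at 24 h, 1370 up and 1066 down, or 3807 (2051 and 1756) with the replicate number as a block. Without the 3 arrays of low 5′ signal it called 3970, with 1 array left at 24 h, which was tested on the spread of the 0 h and 8 h pairs. The count was 988 without 0 h replicate 1, 936 without 0 h replicate 2 and 1361 without 24 h replicate 1.

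**Figure D3:**
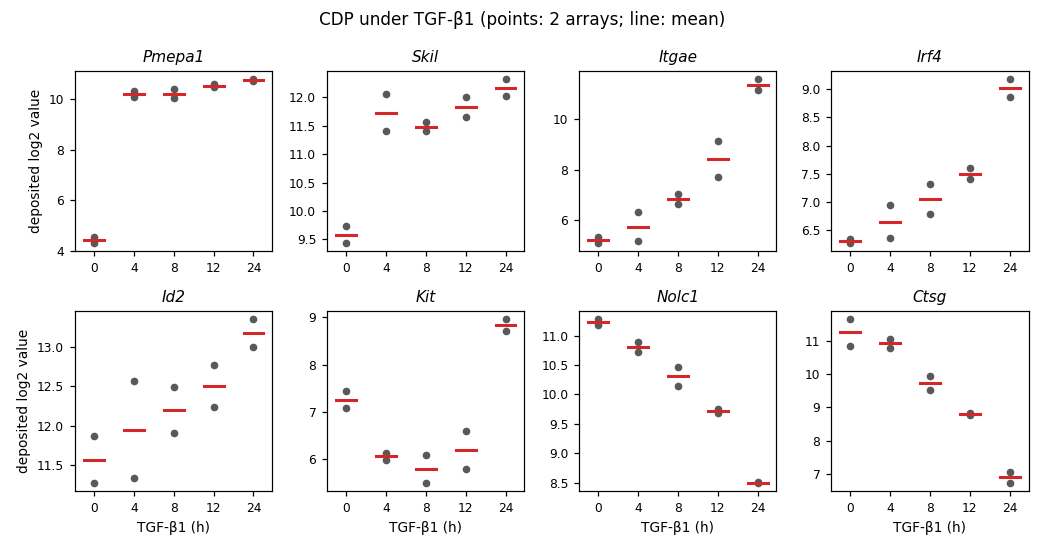
Log2 expression of 8 genes in cultured CDP by hours of TGF-β1, with points for the 2 arrays and a line through their means. Pmepa1 and Skil are up at 4 h, Itgae and Irf4 climb up to 24 h, and Kit is lower at 4 to 12 h than at 24 h.

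At 4 h Pmepa1 stood at 10.21 ± 0.18 against 4.44 ± 0.18 at 0 h (at least 36.9-fold, SE 0.19 on the log2 scale, adjusted p = 2.02e-05), and it kept 10.21 at 8 h and 10.53 at 12 h. Rasgrp3 rose at least 13.6-fold and the desmosome gene Dsp at least 1.71-fold at 4 h, with Emp1 up 5.60-fold and Tgfbr1 5.36-fold (all adjusted p = 0.00188), and Skil up by 2.14 (adjusted p = 0.0130). Dsp was at least 6.22-fold above 0 h at 8 h and at least 15.9-fold at 12 h. Klf2 fell by 1.63 at 4 h, 1.30 at 8 h and 1.49 at 12 h. Flt3 was up by 0.91 at 8 h (adjusted p = 0.0343), Cdh1 by 3.38 at 8 h (adjusted p = 0.00411), and Itgae by 3.23 and Irf4 by 1.19 at 12 h (adjusted p = 0.0119 and adjusted p = 0.0369). Ctsg fell by 1.52 at 8 h (adjusted p = 0.0486) and by 2.46 at 12 h, and Nolc1 by 0.92 and 1.51.

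Some early calls were gained with the replicate number as a block, which may also take up the low 5′ signal of replicate 1 at 4 and 12 h. Smad7 differed by 1.68, 1.46 and 1.87 at 4, 8 and 12 h, with adjusted p = 0.329, 0.251 and 0.0671, or 0.0150, 0.0161 and 0.00288 blocked. Kit differed by -1.21, -1.48 and -1.07, with adjusted p = 0.228, 0.0666 and 0.0939, or 0.0452, 0.0110 and 0.0173 blocked. Tgfbr2 at 4 h (1.29, adjusted p = 0.112) passed at 0.0105 when blocked, Irf8 at 8 h (1.01, adjusted p = 0.172) at 0.00922 and at 12 h (0.78, adjusted p = 0.193) at 0.0119, and Id2 at 12 h (0.93, adjusted p = 0.308) at 0.0250. Without the 3 arrays of low 5′ signal Smad7, Kit and Irf8 passed at 8 h, where both arrays remained, with the spread taken from the 0 h and 8 h pairs alone. At 4 and 12 h 1 array each was left, so these times were not judged on that fit.

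Among the lists, immediate early genes were already lower at 4 h, with a median of -0.81 and 1 of 16 past the threshold (4 adjusted over the list alone; adjusted p = 4.05e-07; adjusted p = 0.0348 with an estimated correlation). The SMAD list had 5 of 23 up at 4 h (6 up and 3 down adjusted over the list alone; adjusted p = 0.00779; adjusted p = 0.152 with an estimated correlation) and 5 up and 1 down at 8 h (8 and 2 adjusted over the list alone; adjusted p = 4.10e-05; adjusted p = 0.0459 with an estimated correlation). MYC and ribosome biogenesis genes had medians of -0.32 at 4 h, -0.69 at 8 h and -0.98 at 12 h. Of these 20 genes 2 fell at 8 h (7 adjusted over the list alone; adjusted p = 1.14e-08; adjusted p = 0.0459 with an estimated correlation) and 6 at 12 h (11 adjusted over the list alone; adjusted p = 6.01e-11; adjusted p = 0.0440 with an estimated correlation). Sterol synthesis genes rose at 8 h with a median of 0.93 and 1 of 17 past the threshold (12 adjusted over the list alone; adjusted p = 8.13e-10; adjusted p = 0.0459 with an estimated correlation). MHC class II genes had a median of 0.73 at 8 h with 0 past limma's adjusted threshold and 5 past an unadjusted one (3 adjusted over the list alone; adjusted p = 1.15e-04; adjusted p = 0.0760 with an estimated correlation). At 12 h, 3 of 14 rose (6 adjusted over the list alone; adjusted p = 2.22e-04; adjusted p = 0.0837 with an estimated correlation). Cytokine receptors rose for 3 of 19 at 8 h (6 up and 1 down adjusted over the list alone; adjusted p = 5.96e-04; adjusted p = 0.0459 with an estimated correlation), while at 12 h the list passed with the block (adjusted p = 0.0538, or 0.0241 blocked; adjusted p = 0.252 blocked with an estimated correlation). The cDC markers at 8 h likewise passed when blocked (adjusted p = 0.0610, or 0.0324 blocked; adjusted p = 0.278 blocked with an estimated correlation), as did the cell cycle list (adjusted p = 0.0726, or 0.0417 blocked; adjusted p = 0.314 blocked with an estimated correlation). In the blocked fit with an estimated correlation camera called 0 of 19 lists at each of 4, 8, 12 and 24 h, with 3, 8, 6 and 6 at an unadjusted p, so the list calls with an estimated correlation at 4, 8 and 12 h were lost there.

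Limma called 82 genes at 4 h, 72 of them up and 10 down (121 and 32 blocked), 196 at 8 h, 152 up and 44 down (354 and 212 blocked), and 679 at 12 h, 466 up and 213 down (951 and 583 blocked). The F-test over the 4 times called 1232 genes, or 2580 blocked. Without the 3 arrays of low 5′ signal the counts were 143, 1213 and 1603, and 2411 for the F-test. In that fit 4, 12 and 24 h held 1 array each, and all spread came from the 0 h and 8 h pairs, whose replicate SDs were the smallest of the 5 groups. Leaving out single arrays gave at 4 h 17 without either 0 h array, 42 without 4 h replicate 1 and 1321 without 4 h replicate 2, and at 8 h 58 and 42 without 0 h replicates 1 and 2 and 44 and 41 without 8 h replicates 1 and 2. At 12 h it gave 118 and 125 without 0 h replicates 1 and 2, and 186 and 194 without 12 h replicates 1 and 2. The F-test gave 362 and 348 without 0 h replicates 1 and 2, 2952 without 4 h replicate 2, 666 without either 8 h array, 798 without 12 h replicate 1, and 547 and 529 without 24 h replicates 1 and 2.

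The difference between the late and the early response was tested by setting 24 h against 4 h. Itgae was higher at 24 h by 5.65 (adjusted p = 0.00122), Irf4 by 2.38 (adjusted p = 0.00181), Gna14 at least 45.1-fold and Dsp by 3.51 (both adjusted p = 6.21e-05). Kit was higher by 2.80 (SE 0.30, adjusted p = 0.00184). Ctsg and Nolc1 were lower by -4.05 and -2.31 (both adjusted p = 4.54e-04). Skil (0.44, adjusted p = 0.317) and Smad7 (0.47, adjusted p = 0.582) did not pass, and Tgfbr1 (0.51, adjusted p = 0.124) passed at 0.0389 when blocked. Of 19 cDC markers 10 were higher (11 adjusted over the list alone; adjusted p = 2.27e-05; adjusted p = 0.0503 with an estimated correlation), as were 10 of 14 MHC class II genes (10 adjusted over the list alone; adjusted p = 5.38e-07; adjusted p = 0.0503 with an estimated correlation). Of 20 MYC and ribosome biogenesis genes 10 were lower (15 adjusted over the list alone; adjusted p = 4.28e-11; adjusted p = 0.0503 with an estimated correlation), as were 8 of 29 cell cycle genes (9 adjusted over the list alone; adjusted p = 3.14e-04; adjusted p = 0.0503 with an estimated correlation).

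Limma called 1625 genes between 24 h and 4 h, 963 higher and 662 lower at 24 h (1712 and 1312 blocked). The share of higher genes was 59.3%, or 48.1% with median centring, and the count was 823 and 711 without 24 h replicates 1 and 2, and 2764 without 4 h replicate 2.

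**Figure D4:**
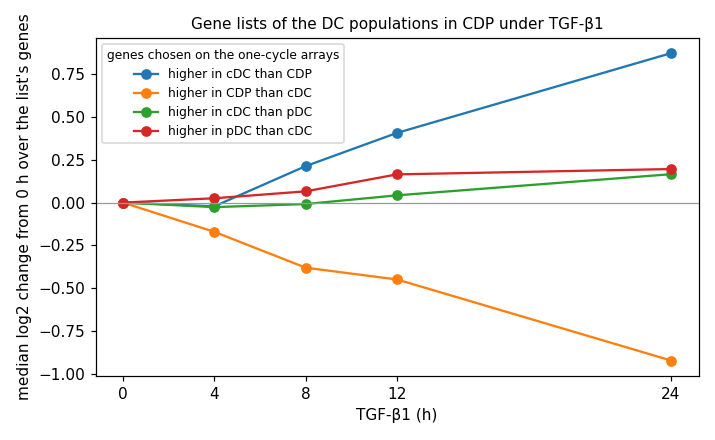
Median log2 change from 0 h of 4 gene sets chosen on the one-cycle arrays, by hours of TGF-β1. At 24 h, genes higher in cDC than CDP reach 0.87 and genes higher in CDP than cDC fall to -0.92. Genes higher in cDC than pDC stand at 0.17 and genes higher in pDC than cDC at 0.20.

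Whether CDP moved along the path to cDC during TGF-β1 treatment was tested with genes called between cDC and CDP on the other arrays with a log2 difference of at least 2. Of 484 measured genes higher in cDC than in CDP, 227 rose and 18 fell at 24 h, with a median of 0.87 (adjusted p = 3.45e-22; adjusted p = 0.00534 with an estimated correlation). Of 473 genes higher in CDP, 213 fell and 16 rose, with a median of -0.92 (adjusted p = 3.98e-24; adjusted p = 9.65e-04 with an estimated correlation). The medians of the former were -0.02, 0.21 and 0.41 at 4, 8 and 12 h, and those of the latter -0.17, -0.38 and -0.45. Across 8765 genes, which are not independent replicates, the 24 h change correlated with the difference between cDC and CDP (Pearson r = 0.53, Spearman rho = 0.55) and with that between pDC and CDP (0.49 and 0.50). Without the 3 arrays of low 5′ signal, which left 1 array at 24 h, the medians were 0.94 and -0.97.

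Both sets of genes that separate the dendritic cell types had small positive medians. Of 396 genes higher in cDC than in pDC, 109 rose and 65 fell at 24 h, with a median of 0.17 (adjusted p = 0.0327; adjusted p = 0.321 with an estimated correlation). Of 303 genes higher in pDC, 87 rose and 41 fell, with a median of 0.20 (adjusted p = 0.00844; adjusted p = 0.0444 with an estimated correlation, or 0.0733 with the estimated correlation in the blocked fit). The difference between both sets was not tested. Across the 8765 genes the 24 h change had r = -0.02 and rho = -0.05 with the difference between cDC and pDC, and r was -0.08 without cDC replicate 2. The call for genes higher in cDC was lost without cDC replicate 1 (adjusted p = 0.122), cDC replicate 2 (0.334), 0 h replicate 2 (0.108) or 24 h replicate 1 (0.102), and the median of the genes higher in pDC was 0.12 without pDC replicate 2. Without the 3 arrays of low 5′ signal, which left 1 array at 24 h, the medians were 0.17 and 0.26.

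CDP taken from bone marrow were compared with the cultured CDP of the same part of the table. The AP-1 gene Fosb was at least 33.2-fold, the heat shock gene Hspa1a at least 37.6-fold and Egr1 91.4-fold higher in vivo (adjusted p = 1.01e-06 for Fosb and 0.00440 for Egr1). Mpo was 40.9-fold higher (SE 0.16 on the log2 scale, adjusted p = 1.09e-06) and Elane at least 5.04-fold, and the scavenger receptor Cd163 at least 13.7-fold. Asns was 240-fold lower (SE 0.71, adjusted p = 1.10e-04), with Cth at least 43.5-fold, Trib3 at least 38.4-fold and lipoprotein lipase (Lpl) at least 65.8-fold lower. Irf8 was 9.08-fold higher (SE 0.25, adjusted p = 6.24e-05), Kit higher by 2.67 and Flt3 by 1.83, while Id2 fell by 2.83 (SE 0.36, adjusted p = 5.46e-04). Tcf4 fell by 0.81 (SE 0.18, adjusted p = 0.00648), while another probe set of the gene differed by 0.36 in the other direction.

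Of 19 immediate early and stress genes, 16 were higher in vivo and 1, Socs3, lower by -4.64, with the same counts adjusted over the list alone (median 4.06, adjusted p = 7.84e-05; adjusted p = 0.965 with an estimated correlation). Of 17 sterol synthesis genes 10 were lower (12 adjusted over the list alone), with Msmo1 at -3.10 and Scd1 at least 13.8-fold lower (median -1.50, adjusted p = 4.78e-04; adjusted p = 0.965 with an estimated correlation). Granulocyte markers split into 8 higher and 2 lower of 14, the latter including Ms4a3 at -3.33 (median 2.69, adjusted p = 0.30). Without a list call, receptors had 8 of 17 higher and 2 lower, with Il6ra 10.2-fold higher and Tgfbr2 at -3.10, and stem and progenitor genes 6 of 18 higher and 1 lower, with Cd34 up by 2.27 and Hoxa9 at -2.19 (median 0.35). Against CDP of the same kit after quantile normalization the stem and progenitor list turned, with 3 higher and 7 lower of 20 and a median of -0.28. MHC class II genes had 4 higher and 4 lower of 14, with H2-DMa at 3.60 and H2-Aa at -2.38, and pDC markers 6 higher and 3 lower of 17. The cDC markers had 6 higher and 4 lower of 19, the SMAD list 5 and 3 of 21, maturation genes 3 and 3 of 14, MYC genes 3 and 6 of 20, cell cycle genes 2 and 4 of 29, and monocyte markers 2 and 3 of 12. Interferon genes had 3 higher of 18 and mast cell markers 1 lower of 7. Against the same-kit reference the median of cell cycle genes went from 0.07 to -0.13 and that of mast cell markers from -0.04 to 1.19, and 11 MYC genes were lower. Median and mean differed in sign for MHC class II genes (-0.10 and 0.07) and the SMAD list (0.05 and 0.00).

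Limma called 4298 of 9122 genes, 2520 higher and 1778 lower in vivo, a share of 58.6% higher that was 46.1% with median centring and 49.3% with quantile normalization; the all-gene median of 0.10 became -0.11 with centring. The count was 2817 without in vivo replicate 2. Labelling kit, RNA amount (50 ng against 1 µg), extraction kit and cell source differed together, and Gapdh and the transferrin receptor had larger 3′ to 5′ differences in vivo, so they cannot be told apart. Against the CDP at 0 h, labelled with the same kit, after quantile normalization, 3449 of the 9122 genes were called. Of these, 853 were higher and 625 lower in vivo against both references, where independent lists would share 534 and 296 and the common in vivo arrays add to the overlap, and 321 went opposite ways. Against that reference Fosb, Mpo, Irf8 and Kit were called higher and Asns and Trib3 lower in vivo, while Tcf4 (0.21, adjusted p = 0.50), Id2 (-1.03, adjusted p = 0.0770), Flt3 (0.33, adjusted p = 0.242) and Cd34 (0.09, adjusted p = 0.864) did not pass.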

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

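The tests on beta-actin and on the labelling kit were chosen after the results they concern were seen, and so was the removal of the 3 arrays with low 5′ signal.

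The TGF-β1 response differed between late and early times by a direct test of 24 h against 4 h, which called 1625 genes, and 9 of 19 lists by camera. Kit was among them, below 0 h at 4 h (-1.21, not past the threshold) and above it at 24 h (1.59), a difference of 2.80. The gene count was 823 without 24 h replicate 1, 711 without 24 h replicate 2 and 2764 without 4 h replicate 2. With an estimated correlation camera called 0 lists after adjustment and 5 at an unadjusted p.

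Control probe sets, which were not among the genes tested and entered a fit only as the Gapdh covariate, set replicate 1 at 4, 12 and 24 h apart, with 3′ minus 5′ Gapdh differences of 2.09, 2.61 and 2.78. Their smallest beta-actin difference exceeded the largest of the other 7 TGF-β1 arrays by 1.54, which is consistent with loss of RNA 5′ ends. A wrong time label was argued against, since 0 of the 3 arrays lay nearest to another time on an axis of 381 genes (for example 0.58 for 12 h replicate 1 beside 0.64 for replicate 2). Whether the ends were lost in the cells, during extraction or during labelling stays open, and no biological explanation was tested.

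Genes higher in pDC than in cDC had a median of 0.20 at 24 h, with 87 up and 41 down (adjusted p = 0.00844; adjusted p = 0.0444 with an estimated correlation, or 0.0733 with it in the blocked fit). Genes higher in cDC had a median of 0.17, with 109 up and 65 down (adjusted p = 0.0327; adjusted p = 0.321 with an estimated correlation, or 0.0733 with it in the blocked fit). The difference between these medians was not tested. The arrays with low 5′ signal were argued against as the source, because the median of the pDC genes was 0.26 without them. That value rests on 1 array at 24 h. Both arrays at 8 h, which had no low 5′ signal, had higher means of these genes (7.75 and 7.83) than those at 0 h (7.58 and 7.61). Their median change at 8 h was only 0.07, with 53.5% of the genes above 0. The argument therefore rests mainly on the 1 array at 24 h. The positive medians may in part reflect genes gained in both cell types. The 49 pDC genes also higher in cDC than in CDP had a median 0.60 above the other 254 (95% bootstrap interval 0.31 to 1.13). The 30 cDC genes also higher in pDC than in CDP stood 1.58 above the other 366 (0.86 to 2.56). Both intervals resample genes, which are not independent replicates, so they do not measure spread between arrays. The other 254 and 366 genes had medians of 0.09 and 0.14, with 52.4% and 55.7% of them above 0. These remainders were not tested on their own, so whether shared genes account for all of either median stays open. Across all genes the 24 h change also correlated with the difference between cDC and CDP (r = 0.53), and the split cannot be told apart from that correlation. A part played by genes gained in both cell types stays a hypothesis, since it was found and tested on the same TGF-β1 arrays. Hours in culture, which went with TGF-β1, stay open as well.

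Immediate early and stress genes were higher in in vivo CDP for 16 of 19, with a median of 4.06 (adjusted p = 7.84e-05; adjusted p = 0.965 with an estimated correlation, by which camera called 0 lists here, adjusted or not). Against CDP of the same kit after quantile normalization the median was 3.46. This argues against the labelling kit as the whole cause only as far as that normalization holds. The same-kit CDP lie in the other part of the table, and untreated CDP of both parts still differed at many genes after it. The value may therefore carry a difference between the parts. Stress from isolating the cells could not be told apart from other differences of source, because a second list of 13 stress genes had a median of 0.48 against one-cycle CDP, between the bounds set beforehand, and of 1.15 against CDP of the same kit after quantile normalization. RNA amount, extraction kit, the larger Gapdh and transferrin receptor 3′ to 5′ differences in vivo and a difference between marrow and culture also stay open. So does the processing of both parts of the table.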

How the results depend on the processing

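The removal of 3 arrays, the Gapdh covariate and the comparison of in vivo CDP with one-cycle CDP were chosen after the data were seen; the other alternatives were planned. Of 7384 values for 584 named gene differences under alternatives, 6694 kept direction and side of the threshold, 573 lost the threshold, 112 gained it and 5 reversed. Of 337 other values, 251 were counted as unchanged. For counts this meant within a fixed ratio of the main count, so such counts could still differ. For the correlation it meant within a fixed distance, and for gene sets the same direction and side of the threshold. The cause of a change was not tested. With another probe set, Klk1 changed to 0.0297 in cDC versus CDP and 6.58 in pDC versus CDP, Id2 to 1.20 in pDC versus CDP, Fdft1 to -0.0680 at 24 h and Tcf4 to 0.36 in vivo.

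Without a filter the counts were 350 for CDP versus MPP, 1483 for cDC versus pDC, 14099 for in vivo CDP versus 0 h and 14740 between kits. Testing all probe sets, which are more numerous than genes, gave 7041 for cDC versus CDP, 8442 for pDC versus CDP, 3647 for cDC versus pDC, 3766 at 24 h, 18890 for in vivo CDP versus 0 h, 7716 against one-cycle CDP and 19770 between kits. Quantile normalization gave 3498 for in vivo CDP versus 0 h and 4913 between kits, and one-cycle CDP as the reference in a fit of all arrays gave 4174.

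With the replicate number as a block the counts were 153 at 4 h, 566 at 8 h, 1534 at 12 h, 3807 at 24 h, 3024 for 24 h versus 4 h and 2580 for the F-test. Without the 3 arrays of low 5′ signal, with the lone arrays at 4, 12 and 24 h assumed to vary like the 0 h and 8 h pairs, they were 143, 1213, 1603 and 3970 at the 4 times and 2411 for the F-test, and camera called 9 lists at 4 h. The Gapdh covariate gave 204, 876, 1800 and 3916, 3986 for 24 h versus 4 h and 3058 for the F-test.

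The genes higher in cDC than pDC lost their call at 24 h with a filter at 6 (median 0.16, adjusted p = 0.0883), a list difference of 1 (0.12, adjusted p = 0.138), an estimated correlation (0.17, adjusted p = 0.321), without the 3 arrays (0.17, adjusted p = 0.127) and with the covariate (0.17, adjusted p = 0.0750). With an estimated correlation, camera called 0 lists for CDP versus MPP (3 unadjusted), cDC versus CDP (1), pDC versus CDP (1), cDC versus pDC (2), 24 h (8), 24 h versus 4 h (5) and in vivo versus one-cycle CDP (0 unadjusted). It called 1 at 4 h, 6 at 8 h, 2 at 12 h and 1 for in vivo CDP versus 0 h.

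Leaving out 1 array, with the lone sample assumed to vary like the other groups, gave 208 to 468 genes for CDP versus MPP, 2938 to 3767 for cDC versus CDP, 3622 to 4218 for pDC versus CDP and 1262 to 1599 for cDC versus pDC. It gave 17 to 1321 at 4 h, 41 to 58 at 8 h, 118 to 194 at 12 h, 936 to 1724 at 24 h, 711 to 2764 for 24 h versus 4 h and 348 to 2952 for the F-test. In vivo counts were 2817 to 3677 against one-cycle CDP and 7406 to 7688 against 0 h, and counts between kits 8338 to 8743. Medians at 24 h were 0.11 to 0.24 for genes higher in cDC than pDC, 0.12 to 0.24 for genes higher in pDC, 0.83 to 1.03 for genes higher in cDC than CDP and -0.99 to -0.86 for genes higher in CDP. The correlation with the difference between cDC and pDC was -0.0844 to -0.00487. Signal near the floor limits folds of genes under 5, which are bounds. On the TGF-β1 arrays folds from levels just above 5 are uncertain as well.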

Other observations

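Both second lists below were written before their values were seen, but the patterns that led to them were noticed in the data.

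Trib3, Cth and Asns, targets of the response to amino acid shortage, were lower in cDC, pDC and in vivo CDP than in cultured CDP. This may reflect a shortage of amino acids or a related stress in the progenitor culture. A second list of 23 measured targets had medians of -3.18 in cDC (20 lower, 1 higher), -2.97 in pDC (19 lower, 1 higher) and -1.16 in vivo (15 lower, 1 higher). The smaller of its median excesses in cultured CDP over cDC and over in vivo CDP was 1.16, and single members went the other way, such as Cebpb, which was higher in vivo by 2.25. The serine synthesis gene Psat1 differed by -4.18 in cDC and -1.86 in vivo. Phgdh differed by -5.34 in cDC but by 0.34 in vivo (limma adjusted p = 0.246), and Ddit4 was higher in cDC by 0.86. Ddit3 and Sesn2 did not pass in cDC (0.18 and -0.16) or pDC (-0.38 and -0.46). In vivo Sesn2 was lower, at -0.97, and Ddit3 (0.84) did not pass. Labelling kit, RNA amount and extraction kit differed along with cell source in that comparison. The list median fell by 0.98 under TGF-β1 at 24 h, with 7 lower and 1 higher. Slower growth of cDC and pDC would lower synthesis genes as well and was not tested apart from it.

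Cdh1, Cldn1 and Dsp, genes of epithelial contacts, were higher after 24 h of TGF-β1 than at 0 h. Whether they belong to a wider adhesion programme stayed open. Of 21 genes of a second epithelial list, 12 passed the filter on low values, with a median change of 0.68, 6 up and the others not past the threshold. The filter also reads the treated arrays and so favours genes that rose. Without it the median over 19 genes was 0.24, and over the 10 genes above 5 on both 0 h arrays it was 0.36 with 4 up; these filters were chosen after the first value was seen. Tjp1 went from 4.27 to 7.86 and Spint1 from 5.82 to 9.41, Jup rose by 1.59 and Krt18 by 1.73, while Epcam (0.28) did not pass. On the one-cycle arrays the genes differed between dendritic cell types. Cdh1 stood at 3.13 in CDP, 7.36 in cDC and 10.93 in pDC, whereas Hepacam2 stood at 9.29 in cDC and 2.26 in pDC, Cldn1 at 6.51 and 2.25, and Spint1 at 7.15 and 2.25.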
